A study of Mus musculus with 87 samples.

How the data were processed

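Libraries of C57BL6 mouse tissues were measured by massively parallel signature sequencing. Total RNA was checked on a Bioanalyzer, complementary DNA was cut with DpnII, and the 20 bases at the 3′-most DpnII site were cloned and sequenced on microbeads, per the labels' protocols. The deposited files hold whole bead counts per signature and run, per the file headers, whose totals equal the column sums to within 0.1%. The labels speak of values converted to tpm, but the deposited files hold counts, and no scaling had been applied to them. How signatures were filtered before deposit is not stated. Of 87 samples, 81 had a file, and 6 were not analysed here. Of the 81 libraries, 70 came from 35 tissues with a male and a female library and 11 stood alone. Groups were taken from the titles.

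Signatures written in upper and lower case were merged, and the runs of a library were summed, since a run is not a replicate. The depth was between 1935158 and 3014680 counts per library. A count of 0 allows up to 3 counts of the total, between 0.995 and 1.55 CPM, and intervals are exact binomial intervals at 95%, which cover counting error only. Since no transcript sequences were available, each signature is a feature, and gene names, gene lists, organ panels and cell type markers were not used here. A signature that 2 transcripts share counts for both, and a transcript can give more than 1 signature. A signature was tested when it reached 5 CPM in at least 2 libraries of the fit.

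Differences between tissues and sexes were tested in 1 fit of the 70 libraries, with terms for tissue and sex, by edgeR 4.0.16 (glmQLFit and glmQLFTest) with trimmed mean of M values (TMM) scaling and Benjamini-Hochberg adjustment within each comparison at 0.05. It tested 74864 signatures. The liver interaction added the male left lobe, with 75406 signatures in 71 libraries. CNS and non-neural tissues were compared over 33 tissues, with the counts of a tissue summed, for 48232 signatures. TMM factors ranged from 0.314 to 1.47. The quasi-likelihood fit used a common dispersion, 1.00 in the 70-library fit, estimated from the most abundant signatures. The form of the dispersion was not fixed in the plan and was chosen for low counts and run time. The prior degrees of freedom of the quasi-dispersion were infinite in the 70-library fit, so each signature was given the spread expected at its abundance. The form with a prior dispersion trend was run as an alternative. A compiled solver replaced edgeR's fitting routine. On 3000 signatures its p-values differed from edgeR's by at most 0.000316 and it made the same calls.

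DESeq2's fit had not converged for 1781 of 74864 signatures in the 70-library fit, and its calls came mostly from these. Further tools were DESeq2 1.42.0, limma 3.58.1, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were bead totals from the labels in place of TMM, W runs only, no filter beyond a count of 1, DESeq2, a 2-fold threshold, fewer libraries, leaving out each library of a compared tissue, and a covariate for T runs. The planned giving of signatures to genes, the pseudocount for values in TPM and the set tests could not be run without a reference or on counts. Leaving out each library in turn was not run for tissue enrichment.

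Signatures named in the text were chosen by a rule set before the data were examined, together with the tests and most of the alternatives. The rule takes the largest log2 changes among calls with a mean of at least 20 CPM in the higher group and the same direction in each sex (no direction rule for sex). Of those, the 2 per direction and comparison printed, or 1 per CNS region, were those with beads in both run types first, a choice made after the data were seen. Values are means with the SD between libraries. A fold against a group with no counts used a floor of 3 counts over the group, and with 1 to 3 counts the ratio carries a counting interval.

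Distinct signatures were compared at the lowest depth of any library, 1935158 counts, by a two-sided permutation test over tissues with 100000 resamples. Agreement was Spearman's correlation across signatures. Splits numbered 100 for CNS and 30 exchanges of libraries within tissues for sex, the real grouping included in each.

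The tests were tested on simulated counts drawn from the means and library sizes, with 200 signatures changed. Of 50 changed 8-fold, the fat comparison recovered 15, the cerebellum comparison 32, sex 49, kidney 12, liver 6 and CNS 32, and no change was called in the wrong direction. At 4-fold these numbers were 3, 13, 44, 4, 0 and 20. At 32-fold they were 30, 41, 48, 29, 18 and 48. Unchanged signatures were called in 7 of 56043 for fat, 83 for cerebellum, 47 for sex, 4 of 60043 for kidney, 1 of 60414 for liver and 2114 of 48032 for CNS. Against the changed signatures recovered, false calls made up more than 0.05 of all calls in every comparison but liver. The rank permutation test was checked apart from these, on 5000 simulated signatures, where it recovered 194 of 200 changed 8-fold and called 9 that were unchanged. This simulation differed from that of the edgeR test, so their numbers cannot be compared.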

Results

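The series measured the transcripts of C57BL6 mouse tissues by massively parallel signature sequencing (MPSS). In MPSS, complementary DNA is cloned on microbeads and 20 bases are read on each bead, starting at the DpnII site (GATC) nearest the 3′ end. The number of beads that share a 20-base sequence, called a signature, measures the abundance of its transcript. Of 87 samples, 81 had a file and 6 were not analysed here. A male and a female library were available for 35 tissues, which made 70 libraries. The tissues were classed here from their titles, which name the tissue but no class. Of these tissues, 11 were classed as central nervous system (CNS) and 22 as non-neural, and eye and pituitary were set apart as neural-related. The other 11 libraries each stood alone, without a replicate. Total counts ranged from 1935158 to 3014680 per library, with a median of 2222511. A library held between 12114 and 69409 distinct signatures, with a median of 25686, and 640762 distinct signatures occurred over all libraries. The files do not pair signatures with gene names, so signatures are given by sequence, and no gene or genome position is assigned to them. Abundance is given as CPM, the usual unit of counts relative to the total of a library. A count of 0 allowed up to between 0.995 and 1.55 CPM, depending on the library. Intervals and limits cover counting error only.

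Each library was summed over between 4 and 7 runs, of 413 runs in all. The files mark 74 libraries with runs of types F and W and 7 libraries with runs of types T and W. The labels do not say what these letters mean. The samples also carry a library version, which differed between libraries of some compared tissues and entered no fit. The libraries with T runs were the male bladder, male esophagus, male kidney cortex, female and male kidney medulla, female heart ventricles and septum, and female white fat. Many abundant signatures were counted almost only in one run type. Among 20935 signatures with at least 500 beads in the 74 libraries of types F and W, 8118 (38.8%) had a rate of beads in one run type under 0.1 of the rate in the other, each relative to all beads of that run type. These signatures held 23.3% of the beads. Of 74864 signatures tested across the paired libraries, 42028 (56.1%) had beads in both run types, the lower rate being at least 0.1 of the higher.

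**Figure D1:**
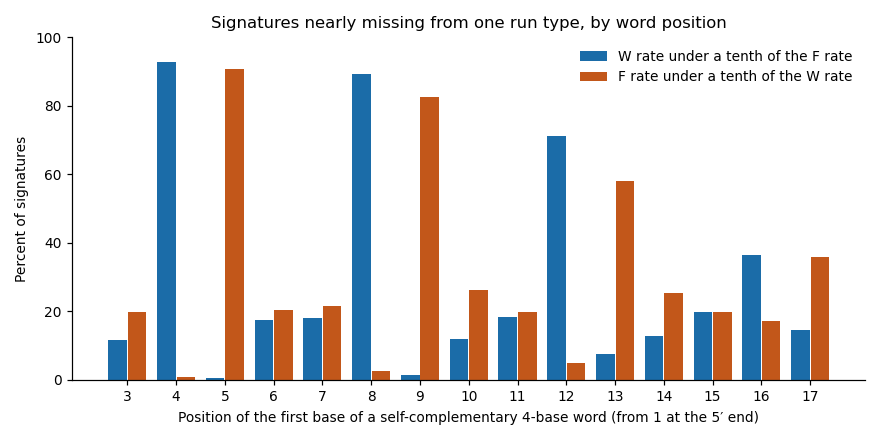
Percent of signatures with at least 500 beads with a rate in W runs under 0.1 of that in F runs, or the reverse, by the position in the signature at which a self-complementary 4-base word starts. Signatures with such a word at position 5 were nearly missing from F runs in 90.8% of cases, and those with one at position 4 from W runs in 92.6%.

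The male and female libraries of a tissue measured how far tissue profiles repeated. Spearman's correlation across signatures between the libraries of a tissue had a median of 0.507 over 35 tissues (SD 0.0563), from 0.422 in heart atria to 0.752 in eye. Signatures are not independent replicates, so no test was made. Between libraries of different tissues the median was 0.358 over 2380 pairs, with a range of 0.25 to 0.634. Eye was the single tissue whose value lay above every value between tissues. The most similar other library came from the same tissue for 35 of the 70 libraries. Among signatures with at least 20 CPM in one library, 31.2% had no count in the other library of the tissue, with a range of 13.4% to 45.7% over tissues. At 200 CPM or more the share was 6.33%, and 72.9% of those signatures had a rate in one run type under 0.1 of that in the other. The libraries of a tissue differed far beyond counting error, with chi-squared values per degree of freedom of 24.5 to 198. The fit of the 70 libraries gave each signature the spread expected at its abundance, shared over all tissues. Its p-values thus do not measure the spread of the compared tissues or of the single signature, which the printed SD shows. The labels name no animals, so the spread between the libraries of a tissue was the only error measured.

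Tissue enrichment, the difference of each tissue from the mean of the other 34, was tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 70 libraries. Over the 35 tissues it gave 168669 calls of higher abundance at an adjusted p under 0.05, from 2413 in thigh skeletal muscle to 7858 in hippocampus. Of these calls, 98153 had counts in both libraries of the tissue. The number depended on the test and the counts used. It was 297975 with a dispersion trend, 109819 with W runs only and 107625 among signatures with beads in both run types. DESeq2 called 6138 higher and 9058 lower, and 8263 of these calls came from fits that had not converged. Lower calls by edgeR were few, from 0 in aorta to 116 in the right lobe of the liver. The higher edgeR calls covered 37952 distinct signatures, of which 18432 (48.6%) were called in 1 tissue and 1327 in at least 10. Each tissue shared more of the calls counted in both libraries with the tissue it shared most with than independent lists would, and the pairs given here were picked for high sharing. Kidney cortex shared 1182 of its signatures (49.3%) with kidney medulla, where independent lists of these sizes would share 106. Heart atria shared 530 (41.8%) with the ventricles, against 33.5 for independent lists. Large intestine shared 595 (47.1%) with small intestine, against 41.2, and spleen shared 759 (37.7%) with mesenteric lymph nodes, against 67.2. The olfactory tubercle, prefrontal cortex and septum shared 2048 (59.0%) with the cortical mantle, against 214. Bladder shared 674 (21.3%) with esophagus, against 98.4, adrenal shared 340 (18.5%) with lung, against 72.5, and the right lobe of the liver shared 311 (22.8%) with kidney medulla, against 60.05. Brown fat shared more with aorta (492) than with white fat (468), and white fat shared the most with bladder (508). The tissues of each pair were compared with largely the same libraries, which adds shared calls. At least 1 library had T runs in each of bladder, esophagus, kidney cortex, kidney medulla, ventricles and white fat. The fit had no term for run type, so sharing among these tissues cannot be told apart from a shared run type. In counts simulated with no tissue difference, the highest number shared by any of the 595 pairs of tissues was 14, and the highest number of calls in a tissue was 644.

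**Figure D2:**
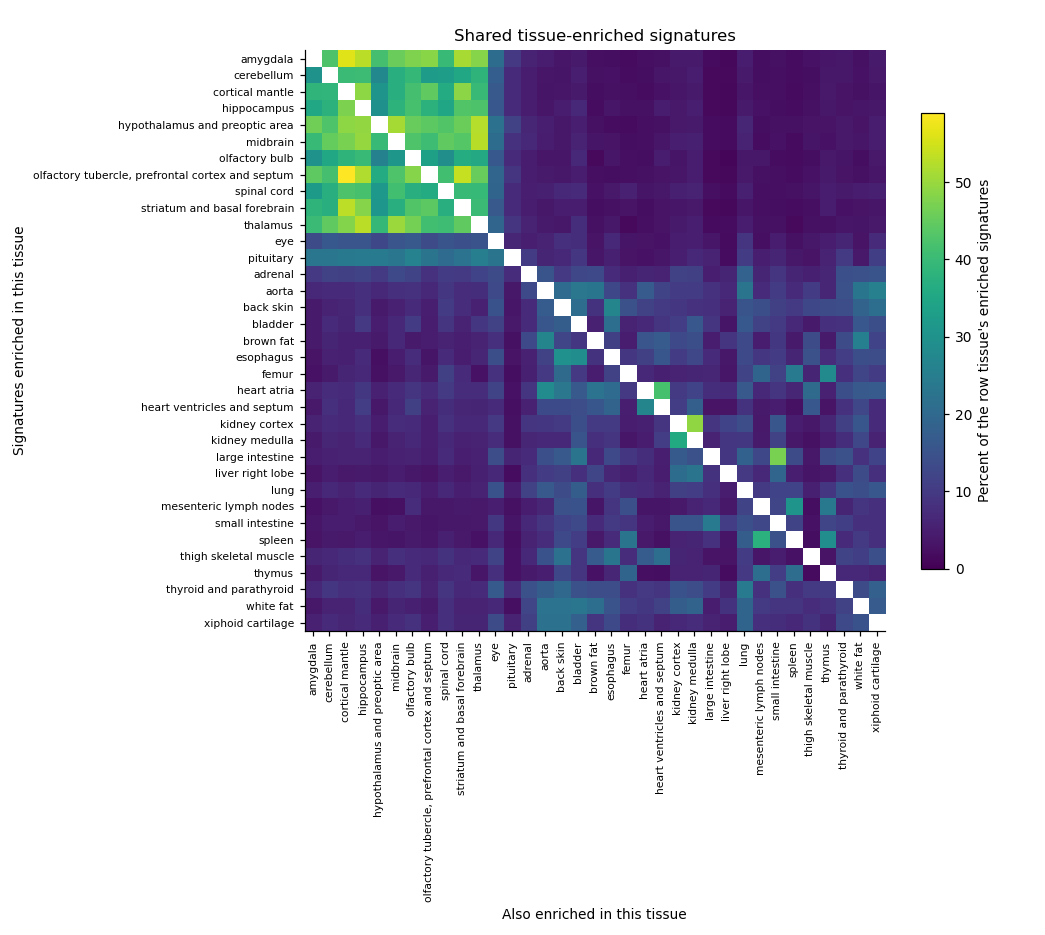
Percent of the signatures enriched in the tissue of each line and counted in both its libraries that were also enriched in the tissue of each column. Kidney cortex shared 49.3% of its signatures with kidney medulla, and the CNS regions formed a block of high sharing.

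The contrast of brown with white fat asked which transcripts set the 2 fat tissues apart. edgeR's quasi-likelihood test called 34 signatures higher in brown fat and 29 higher in white fat at an adjusted p under 0.05, among 74864 tested. Of the 34, 31 were higher in brown fat in each sex, as were 24 of the 29 in white fat. Beads in both run types were found for 19 and 20 of them. The number of calls depended on the test. The same edgeR test with a prior dispersion trend called 1 and 0, DESeq2 called 116 and 158, and an edgeR fit of the 4 fat libraries alone called 0 and 0, with 1021 at an unadjusted p under 0.05. The DESeq2 fit had not converged for 241 of its 274 calls, and this held for most of its calls in every comparison of the 70 libraries. Signature GATCTGACGTGCCGCCGGGC reached 621 ± 653 CPM (SD, n = 2) in brown fat and had no count in white fat, at least 854-fold lower against a limit of 3 counts over the group (adjusted p 5.99e-05). Its level in thigh skeletal muscle was 3212 CPM. GATCAACAAATCTCCTTGGT reached 334 ± 31.6 CPM in brown fat and also had no count in white fat, at least 459-fold lower (adjusted p 0.0407). None of its beads in brown fat came from W runs, and the female white fat library had no F runs, so its absence there cannot be separated from run type. In white fat, GATCACAGAAACAATAAAAG reached 1048 ± 11.2 CPM and was not counted in brown fat, at least 1571-fold lower (adjusted p 0.0183). GATCTGCTTCAATAATTTAA reached 956 ± 1278 CPM in white fat with no count in brown fat, at least 1434-fold lower (adjusted p 1.49e-09). Of its counts over all libraries, 90.02% came from the 7 libraries with T runs, among them the female white fat library. It reached 5879 CPM in heart ventricles and septum. W runs only gave 34 calls and no filter 23. Leaving out 1 library changed the count of 63. It was 28 without the male and 33 without the female brown fat library, and 23 without the male and 30 without the female white fat library. GATCACAGAAACAATAAAAG lost its call without any one of the 4 libraries (adjusted p 0.101 to 1), and GATCTGCTTCAATAATTTAA lost it without female white fat (0.964). GATCTGACGTGCCGCCGGGC lost its call without male (0.0838) or female white fat (0.0706). GATCAACAAATCTCCTTGGT lost it without male white fat (0.436), female white fat (1) or male brown fat (1). Among the 34 signatures higher in brown fat, 14 had their highest level outside fat in thigh skeletal muscle and 7 in heart atria. Among the 29 higher in white fat, 9 had it in the right lobe of the liver and 7 in back skin.

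Between heart atria and ventricles with septum, the same test called 51 signatures higher in atria and 13 higher in ventricles. The direction was the same in each sex for 43 and 8 of them, and 24 and 7 had beads in both run types. The edgeR test with a dispersion trend called 5 and 1, DESeq2 called 267 and 350, and an edgeR fit of the 4 heart libraries alone called 0 and 0, with 215 at an unadjusted p under 0.05. With bead totals in place of trimmed scaling, 35 were called higher and 18 lower. GATCAACAAATCACCTAGGT reached 1348 ± 423 CPM (SD, n = 2) in atria with no count in ventricles, at least 2144-fold lower (adjusted p 7.97e-06). GATCAACAAACAAATCACCT, counted in one run type only, reached 4610 ± 4048 CPM in atria with no count in ventricles, at least 7330-fold lower (adjusted p 3.37e-13). None of its beads in atria came from W runs, and the female ventricle library had no F runs. GATCAACTTATACATCTTCT reached 3076 ± 4058 CPM in ventricles with no count in atria, at least 4667-fold lower (adjusted p 9.52e-07). GATCAGTGTTGAAAGTGCAA reached 888 ± 1254 CPM in ventricles, at least 1347-fold above atria (adjusted p 6.13e-05). For both ventricular signatures the SD exceeded the mean, so 1 library carried most of the counts, and the female ventricle library had T runs. There were 22 calls with W runs only and 36 with no filter. Against 64 calls with all libraries, 18 were made without the female ventricle library and 40 without the female atria library. There were 69 without the male ventricle and 63 without the male atria library. Without the female ventricle library, GATCAACTTATACATCTTCT (adjusted p 0.0577) and GATCAGTGTTGAAAGTGCAA (1) lost their calls. The latter also lost it without the male atria library (0.0621), and GATCAACAAATCACCTAGGT without the female atria library (0.408).

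Between kidney cortex and medulla, 15 signatures were called higher in cortex and 1 higher in medulla. Of the 15, 2 were higher in cortex in each sex and 2 had beads in both run types. The edgeR test with a dispersion trend called 0, with 1090 at an unadjusted p under 0.05, and a fit of the 4 kidney libraries alone called 0, with 127. DESeq2 called 220 and 72. GATCAAACAACCAAACAAAA reached 886 ± 1094 CPM (SD, n = 2) in cortex with no count in medulla, at least 1719-fold lower (adjusted p 2.51e-07). GATCAAACAACCAAACAAAC reached 912 ± 1222 CPM, at least 1769-fold above medulla (adjusted p 1.65e-07). They had counts in 63 and 65 libraries, with 2837 and 4730 CPM in heart atria, so they did not set cortex apart from all tissues. Both had no beads from W runs in cortex. The medulla libraries had no F runs, but neither had the male cortex library, which counted both signatures in T runs. The single signature higher in medulla, GATCGTTTCAAGGTCATGAA, lay outside the rule for naming signatures and was chosen after its values were seen. It had 127 ± 180 CPM in medulla, with a count in 1 of the 2 libraries, and none in cortex (adjusted p 0.0245). The kidney libraries with T runs were both medulla libraries and the male cortex library, so run type and region overlapped in this comparison. A covariate for libraries with T runs gave 2 and 1 calls, of which 2 were among the 16, and among signatures with beads in both run types edgeR called 0, with 1224 at an unadjusted p under 0.05. W runs only gave 1 call, which was none of the 16, and no filter gave 10. Against 16 calls with all libraries, 28 were made without male cortex, 7 without female cortex, 8 without male medulla and 7 without female medulla.

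Between small and large intestine, 38 signatures were called higher in small and 19 higher in large intestine. The direction was the same in each sex for 29 and 16, and 27 and 8 had beads in both run types. The test with a dispersion trend called 0 and 1, DESeq2 called 84 and 206, and an edgeR fit of the 4 intestine libraries alone called 0 and 0, with 476 at an unadjusted p under 0.05. GATCCCCAAGGCGTCAGCCA reached 3035 ± 68.4 CPM (SD, n = 2) in small intestine with no count in large intestine, at least 4031-fold lower (adjusted p 0.000111). GATCCCTGACAGTGCGGACA reached 847 ± 399 CPM in small intestine, at least 1125-fold above large intestine (adjusted p 0.000258). It had 2765 CPM in kidney medulla, so it did not set small intestine apart from all tissues. Libraries with T runs held 65.05% of its counts. GATCGACCCCAACTGGGTGG reached 228 ± 138 CPM in large intestine against 0.207 CPM in small intestine, a ratio of 1102 with a 95% counting interval of 187 to 41311 (adjusted p 0.00553). It had counts in 47 libraries and 1284 CPM in xiphoid cartilage, so it did not set large intestine apart from all tissues. GATCAACAAACAAATCTCCT, counted in one run type only, reached 11173 ± 12802 CPM in large intestine, at least 17304-fold above small intestine (adjusted p 1.29e-17). It had counts in 45 libraries and 6924 CPM in brown fat. The calls fell to 22 with W runs only and to 19 with no filter. Against 57 calls with all libraries, 23 were made without male and 34 without female small intestine, and 19 without male and 22 without female large intestine. GATCCCCAAGGCGTCAGCCA lost its call without male (adjusted p 0.102) or female large intestine (0.169), as did GATCCCTGACAGTGCGGACA (0.0954 and 0.311). GATCGACCCCAACTGGGTGG lost it without male (0.708) or female small intestine (0.611) or male large intestine (0.380).

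Each of the 11 CNS regions was compared with the mean of the other 10, to find signatures that mark a region. The edgeR test gave 5393 calls higher and 50 lower over the 11 regions. Spinal cord had 1016 signatures called higher, olfactory bulb 769, amygdala 664, hippocampus 555, the olfactory tubercle, prefrontal cortex and septum 477, and striatum and basal forebrain 465. Hypothalamus and preoptic area had 416, cerebellum 409, thalamus 256, midbrain 233 and cortical mantle 133. In each sex the direction was the same for 446 in spinal cord, 476 in olfactory bulb, 298 in cerebellum and 174 in amygdala. Over all regions, DESeq2 called 890 higher and 704 lower, and edgeR 2316 in both directions with W runs only and 1201 with no filter. In simulated counts, the cerebellum test recovered 13, 32, 34 and 41 of 50 signatures changed 4-, 8-, 16- and 32-fold and called 83 of 56043 that had not been changed. The share of false calls there lay far above the nominal 0.05, so the counts per region are not held to that rate. Spinal cord signature GATCCTCACAGGTCAGGGGT had 1903 ± 188 CPM (SD, n = 2) against 0.0563 CPM over 20 libraries of other regions, a ratio of 33776 with a 95% counting interval of 9727 to 137907 (adjusted p 1.03e-45). Outside the CNS it reached 241 CPM in back skin. Cerebellum signature GATCTGGAGTTGAAGGCTAG had 1578 ± 526 CPM against 3.14 ± 14.1 CPM, 502-fold higher (adjusted p 4.16e-33). Hypothalamus signature GATCCGTAGCCTTCCCAGCT had 662 ± 96.9 CPM against 3.53 ± 9.70 CPM, 187-fold higher (adjusted p 6.48e-20). Olfactory bulb signature GATCCTTCCAGCAGAGAAAT had 282 ± 110 CPM against 0.653 ± 2.83 CPM, 431-fold higher (adjusted p 2.31e-13). Striatum signature GATCTACTTCCCTGCATAAG had 140 ± 3.95 CPM against 2.02 ± 6.12 CPM, 69.4-fold higher (adjusted p 3.54e-08). Amygdala signature GATCAAAAAACAGGGGAGGA had 82.2 ± 16.1 CPM against 0.141 ± 0.629 CPM, 584-fold higher (adjusted p 1.87e-06). Cortical mantle signature GATCCCTTGTAGAGGCAGAG had 32.3 ± 16.4 CPM against 0.0188 CPM, a ratio of 1720 with a counting interval of 263 to 59067 (adjusted p 0.00628). Hippocampus signature GATCATCGCTCTTCAATCAT had 36.1 ± 8.97 CPM, at least 539-fold above the other regions (adjusted p 0.000109), and 10.8 CPM in brown fat. The signatures printed for the other 3 regions were counted in one run type only. GATCTTTCTGGCTCCCCTCC had 154 ± 52.8 CPM in thalamus, at least 2325-fold above the other regions, and GATCCCCCTCCCCCCCCTGC had 72.2 ± 17.8 CPM in the olfactory tubercle, prefrontal cortex and septum, at least 1096-fold above. GATCATATTGCCCTGCATCT had 45.5 ± 14.6 CPM in midbrain against 0.528 ± 1.97 CPM. It had counts in 20 libraries and 40.5 CPM in adrenal, so it did not set midbrain apart from all tissues. The thalamus signature had 21.3 CPM in thymus, and that of the olfactory bulb 17.05 CPM in thyroid and parathyroid. Leaving out 1 library of a region lowered most counts. Without the female library, amygdala had 329 higher calls, cerebellum 122, cortical mantle 44, hippocampus 90, hypothalamus 88, midbrain 102, olfactory bulb 133, striatum 232 and thalamus 130. Without the male library, cerebellum had 158, cortical mantle 70, olfactory bulb 399, the olfactory tubercle, prefrontal cortex and septum 201, spinal cord 326, striatum 144 and thalamus 96. The hippocampus signature lost its call without the female library (adjusted p 0.157), and the midbrain signature without the male library (0.0604).

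**Figure D3:**
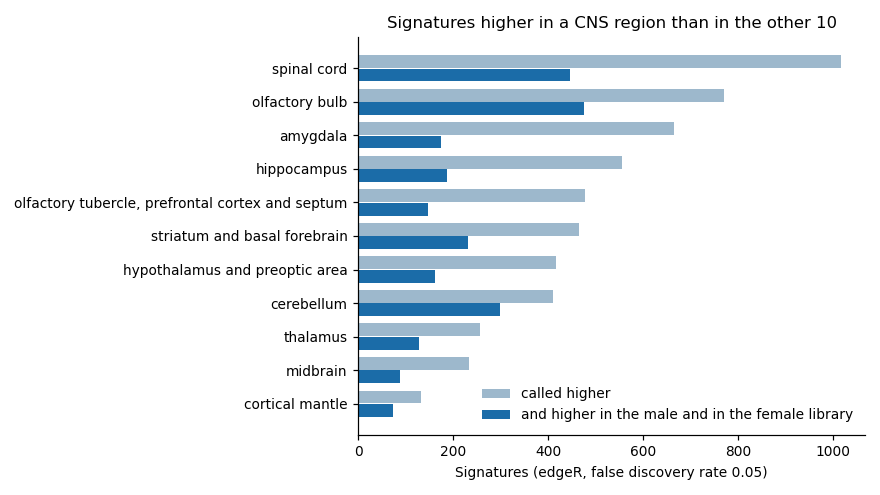
Number of signatures called higher in each CNS region than in the mean of the other 10 by the edgeR test (pale bars), and of those the number higher in the male and in the female library (dark bars). Spinal cord had the most with 1016, of which 446 were higher in each sex, and cortical mantle the fewest with 133 and 74.

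CNS tissues were compared with non-neural tissues, with the 11 and 22 tissues as replicates and the male and female counts of a tissue summed. The edgeR test called 10829 signatures higher in CNS and 11877 lower among 48232. DESeq2 called 6919 and 6411, of which 4043 came from fits that had not converged, and a permutation test of rank sums called 11973 and 1481. Both directions together, edgeR called 22706, against 20110 with W runs only, 13855 among signatures with beads in both run types, 10205 among those in at least 10 tissues and 43015 with no filter. In simulated counts the edgeR test recovered 20, 32, 47 and 48 of 50 signatures changed 4-, 8-, 16- and 32-fold and called 2114 of 48032 that had not been changed. False calls outnumbered true ones there, so the adjusted p does not hold the nominal rate. A set of 8694 signatures was called higher by both edgeR and the rank test. Of these, 1660 had at least 5 CPM in all 11 CNS tissues and 2650 had no count in any non-neural tissue, while 25.3% reached 5 CPM in eye and 17.8% in pituitary. Of the 1465 called lower by both, a larger share did so, 43.8% in eye and 37.0% in pituitary, and the difference was not tested. GATCGCTGACAAAGCGTTCT had 197 ± 68.2 CPM (SD, n = 22 libraries) in CNS, at least 65.7 CPM in each, and no count in 44 non-neural libraries, at least 6687-fold lower (adjusted p 3.09e-12). Eye held 30.1 CPM of it. GATCCAAACTTCCCCCTCTG had 327 ± 1157 CPM in CNS, in 12 libraries, at least 11095-fold above the non-neural libraries (adjusted p 4.66e-06). Its highest library had 5299 CPM, so the mean and the fold rest mostly on 1 library. Lower in CNS, GATCCCTGGTGGAAAGGCGG had 9364 ± 43367 CPM in non-neural libraries against 0.717 CPM in CNS, 13066-fold (adjusted p 5.16e-06). This mean rests mostly on 1 of 44 libraries, which had 224386 CPM. GATCCTTGGGGACGTCTTTT had 683 ± 2228 CPM in non-neural libraries and no count in CNS, at least 11334-fold lower (adjusted p 3.18e-05). Its highest library had 13301 CPM.

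The number of distinct signatures at an equal depth of 1935158 counts compared the variety of signatures. CNS tissues had 36080 ± 7234 (SD, n = 11) and non-neural tissues 22350 ± 4689 (SD, n = 22), a difference of 13730 and a ratio of 1.61. The two-sided permutation test over tissues gave p = 1e-05, the smallest it can give. Among the CNS tissues, 9 of 11 lay above every non-neural tissue, and the hypothalamus and amygdala did not. The female spinal cord library held 67017 signatures at this depth and the male one 32034. Without the female spinal cord library the ratio was 1.54. All 7 libraries with T runs were non-neural, and with W runs only the ratio was 1.64.

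**Figure D4:**
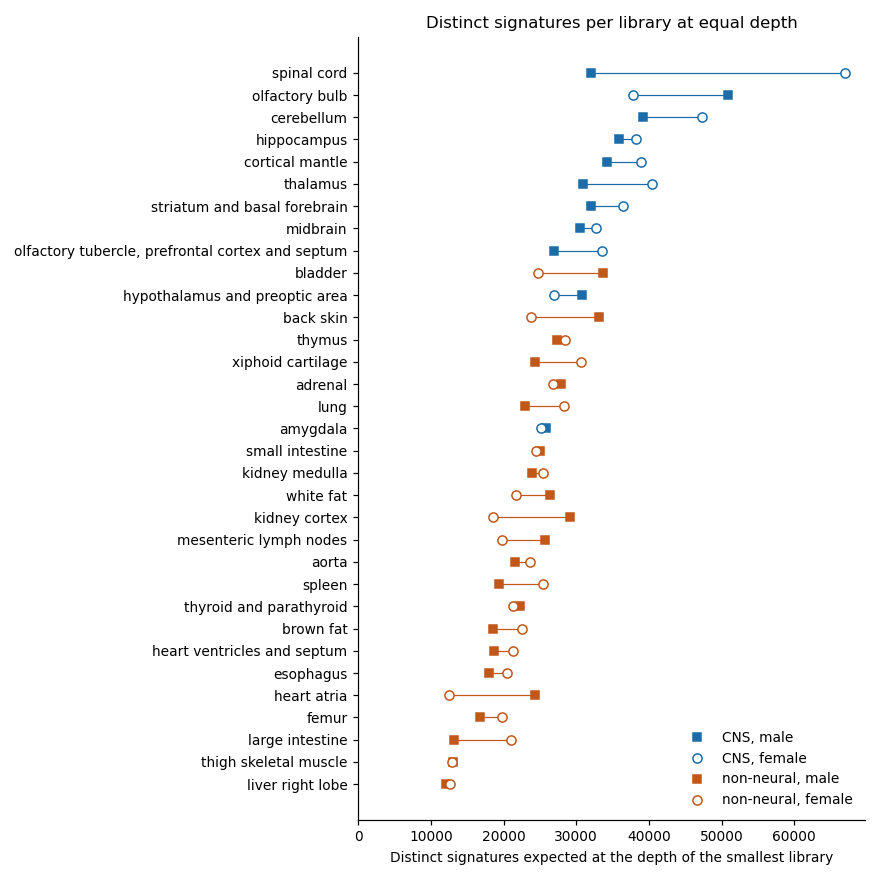
Distinct signatures at equal depth in the male (squares) and female (circles) library of each CNS (blue) and non-neural (orange) tissue, each pair joined by a line. CNS tissues averaged 36080 and non-neural tissues 22350, and the female spinal cord library was the highest at 67017.

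The comparison of male with female libraries over 35 tissues asked which signatures differ by sex in most tissues. The edgeR test called 7 higher in male and 7 higher in female libraries. With a dispersion trend it called 2 and 1, with no filter 3 and 2, with W runs only 4 and 6, of which 4 were among the 14, without the tissues with T runs 12 and 19, and DESeq2 called 132 and 151. In simulated counts the edgeR test recovered 44, 49, 50 and 48 of 50 signatures changed 4-, 8-, 16- and 32-fold and called 47 of 56043 that had not been changed, a share of false calls above 0.05. By the rule for naming signatures, GATCCCACCCACCCACCCAC had 45.4 ± 75.02 CPM (SD, n = 35) in male and 25.9 ± 72.5 CPM in female libraries (adjusted p 0.0476) and was higher in male libraries in 15 tissues and in female libraries in 7. DESeq2 gave it the opposite sign, with a log2 difference of -10.74 (adjusted p 2.63e-06), in a comparison where 277 of its 283 calls came from fits that had not converged. GATCTGCTTCAATAATTTAA had a positive fitted difference within tissues (adjusted p 2.30e-11) but a lower mean in male libraries, 350 ± 995 against 418 ± 2001 CPM, the latter mostly from 1 library with 11758 CPM. It was higher in male libraries in 9 tissues and in female libraries in 2, and 90.02% of its counts came from libraries with T runs. GATCAGGACGATTATTGAGG was higher in female libraries in 24 tissues and in male libraries in 8 (297 ± 1668 against 149 ± 858 CPM; adjusted p 0.0423). Nearly all of these levels came from 1 library of each sex, with 9884 CPM in female and 5081 CPM in male. GATCCAGAAGACGAAAGAAG was higher in female libraries in 19 tissues and in male libraries in 6 (1339 ± 4870 against 1078 ± 4128 CPM; adjusted p 0.0160). Here too 1 library of each sex held most of the level, with 25010 and 23362 CPM. Called signatures below 20 CPM lay outside the rule, and 3 of them were chosen after their values were seen. GATCTTCAGTATGCTGCTCC was counted in 30 male and 2 female libraries, with 13.1 ± 13.4 CPM against 0.244 ± 1.25 CPM (adjusted p 3.47e-06). GATCCAAGCCCTTCATCTTC was counted in 25 male libraries and 1 female library, with 15.4 ± 24.7 CPM against 0.403 ± 2.39 CPM (adjusted p 3.47e-06). GATCTGTGTGGAGCTTTGTG was counted in 17 female and 0 male libraries, with 10.1 ± 18.8 CPM in female libraries (adjusted p 0.000293), and its rate in one run type was under 0.1 of that in the other. The female eye library held both signatures of the male libraries, GATCCAAGCCCTTCATCTTC at 14.1 CPM and GATCTTCAGTATGCTGCTCC at 7.30 CPM, while the male eye library held 13.4 CPM of the former and no count of the latter. The other female library with a count of GATCTTCAGTATGCTGCTCC was small intestine, at 1.24 CPM.

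**Figure D5:**
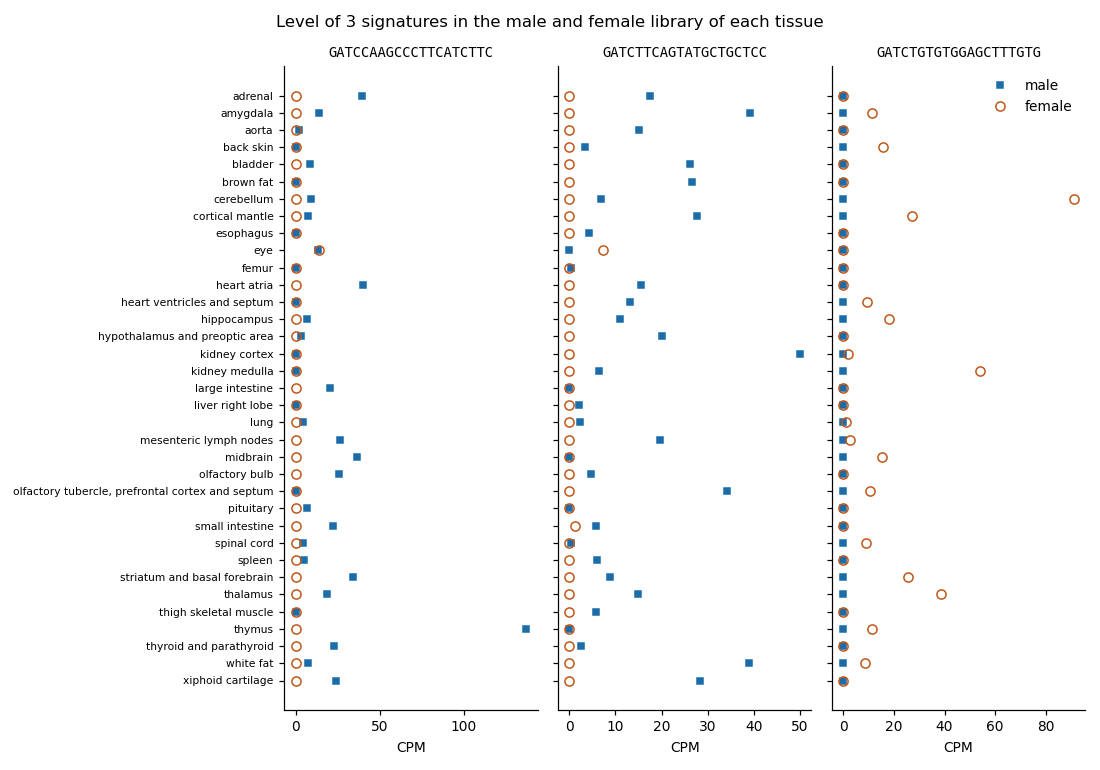
Abundance in CPM in the male and female library of each of the 35 tissues for 3 signatures called by sex. Signature GATCTTCAGTATGCTGCTCC was counted in 30 male and 2 female libraries.

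Whether the sex difference in kidney differed from that in the other tissues was tested as an interaction, with cortex and medulla as the 2 kidney pairs. The edgeR test called 5 signatures with a larger male excess in kidney and 8 with a smaller one, and DESeq2 called 27 and 29. With bead totals in place of trimmed scaling, 2 and 7 were called. There was 1 call with W runs only, 1 with no filter and 3 with a covariate for T runs. GATCAACAAATCTCCTAGTC had 1961 ± 344 CPM (SD, n = 2) in male and 65.3 ± 92.4 CPM in female kidney libraries, against 157 ± 326 and 215 ± 615 CPM in 33 other tissues (adjusted p 0.0482). GATCGAAAACATCACAAATG had 21.0 ± 10.6 CPM in male kidney libraries and no count in female ones, against 804 ± 3361 and 619 ± 1982 CPM in other tissues (adjusted p 0.0329). GATCACCGACCGCATCGAGA had 56.9 ± 80.5 CPM in male and 1678 ± 2067 CPM in female kidney libraries, against 963 ± 495 and 1049 ± 648 CPM elsewhere (adjusted p 0.0117). GATCAGGGCAATGGTCACTG had 34.1 ± 48.2 CPM in male and 187 ± 161 CPM in female kidney libraries, against 5176 ± 26012 and 3242 ± 11445 CPM elsewhere (adjusted p 0.0144). Of the 4 kidney libraries, the 3 with T runs included both male libraries. The female cortex library also had another library version than the other kidney libraries. DESeq2 gave the opposite sign for GATCAACAAATCTCCTAGTC (log2 -1.06) and GATCAGGGCAATGGTCACTG (12.88), neither called. Without the cortex pair 1 signature was called, and without the medulla pair 6. GATCAACAAATCTCCTAGTC lost its call without the cortex pair (adjusted p 1), GATCAGGGCAATGGTCACTG without the medulla pair (1), and GATCGAAAACATCACAAATG and GATCACCGACCGCATCGAGA without either.

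The same interaction for liver set 2 male libraries, of the left and the right lobe, against 1 female library. No spread between female livers was measured, and the p-values take it from the other tissues, so the calls are not a finding on sex. The female library also had another library version than both male ones, so sex and version cannot be told apart in liver. The edgeR test called 9 signatures with a larger male excess in liver and 3 with a smaller one, and DESeq2 called 282 and 8. With W runs only, 1 signature was called and none of the 12 was among it, and with no filter edgeR called 0, with 804 at an unadjusted p under 0.05. GATCAAACAACCCAACAAAC had 351 ± 85.8 CPM (SD, n = 2) in male liver and no count in the female library, at least 282-fold lower (adjusted p 0.00304). GATCCCACTGCACATAGGAA had 1040 ± 1373 CPM in male liver and no count in the female library, at least 837-fold lower (adjusted p 0.025). GATCGAAACTCTCTTCAAGT had 1.24 ± 1.75 CPM in male liver and 100.3 CPM in the female library (adjusted p 0.0223). GATCGTGATTGTGCTGGGCC had 45.7 ± 64.7 CPM in male liver and 533 CPM in the female library (adjusted p 0.0223). DESeq2 gave it the opposite sign, a log2 value of 37.02 (adjusted p 4.63e-40), where 276 of its 290 calls came from fits that had not converged. Leaving out either male liver library gave 6 calls. GATCCCACTGCACATAGGAA and GATCGTGATTGTGCTGGGCC lost their calls without the left lobe (adjusted p 1 for each), and GATCGAAACTCTCTTCAAGT without the left lobe (0.188) or the male right lobe (1). With bead totals in place of trimmed scaling, 3 were called higher and 4 lower.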

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

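The tests of bead sampling and of sequencing errors for the run types, the test of depth for the spinal cord, and the comparison with exchanged libraries for single sex signatures were chosen only after the results were seen.

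The sex difference in kidney differed from that in the other tissues for 13 signatures by edgeR's interaction test. The fitted difference, on the log2 scale, was 9.65 for GATCGAAAACATCACAAATG and 7.37 for GATCAACAAATCTCCTAGTC, where the male excess was larger in kidney. It was -5.90 for GATCACCGACCGCATCGAGA and -4.42 for GATCAGGGCAATGGTCACTG, where it was smaller. A count of 0 lies behind the first value, so its size depends on the fit and is no bound. Both male kidney libraries and 1 of the 2 female ones had T runs, so sex and run type overlapped in kidney. Sex also overlapped with library version, since only the female cortex library had another version. With a covariate for T runs 3 signatures were called, of which 2 were among the 13. W runs only gave 1 call and no filter 1, each among the 13.

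edgeR's interaction test called 12 signatures for liver, with 2 male libraries, of different lobes, and 1 female library. No spread between female livers was measured, and the female library had another library version than the male ones, so the calls are not a finding on sex. The fitted difference was 14.84 for GATCAAACAACCCAACAAAC and 14.39 for GATCCCACTGCACATAGGAA, both without a count in the female library. It was -6.21 for GATCGAAACTCTCTTCAAGT and -3.99 for GATCGTGATTGTGCTGGGCC. The value of GATCGTGATTGTGCTGGGCC rested on 1 female library, and DESeq2 gave it the opposite sign. With W runs only 1 signature was called, which was none of the 12, and with no filter edgeR called 0, with 804 at an unadjusted p under 0.05. DESeq2 called 290.

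Many abundant signatures were counted almost only in one run type. Sampling of few beads does not account for this, because only 61.2% of signatures with at least 500 beads had a rate in each run type of at least 0.1 of that in the other, where sampling would leave nearly all of them above it. Errors of more abundant signatures stay open, since their share lay between the bounds set for the test. Of the signatures with a rate in one run type under 0.1 of the other, 25.2% were 1 base from one with 10 times the beads, against 6.72% of the others. A candidate explanation is a self-complementary 4-base word in the reading frame of one run type. Of the frames named in advance, word starts at 5, 9, 13 and 17 had a median W share of 0.988, the rate in W runs over the sum of both rates, and word starts at 3, 7, 11 and 15 had 0.467, a difference of 0.521. The second frame showed no shift from signatures with a word in neither of these frames, which had 0.464. Those signatures include words at other starts, so they are no baseline free of such words. A deficit in W runs appeared instead at word starts 4, 8, 12 and 16, where 92.6%, 89.2%, 71.1% and 36.3% were nearly absent from W runs, and this was seen only afterwards. The test was not run on another series, no biological explanation was tested, and the labels do not say what the run types are.

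The female spinal cord library held 69409 signatures, the most of any library, and the male one 33142. Greater depth does not account for this, since at equal depth the female library held 2.09 times as many, 67017 against 32034, and the next highest of the other 80 libraries held 50941. Errors of 1 base in signatures with 10 times the beads do not account for it either. The female library held 524 more signatures 1 base from such a signature, 1.45% of the surplus of 36267 signatures. Errors of more bases, or of less abundant signatures, were not tested. Signatures of other tissues mixed into the library remain open. Of the surplus, 12.6% was found in another tissue at 5 CPM or more, between the bounds set before the test. At 5 CPM or more the female and male libraries held 16151 and 15088 signatures, so the surplus lay mostly among rare signatures. Seen in no other of the 81 libraries were 34546 signatures of the female library and 5957 of the male one. A sex difference in spinal cord stays open and was not tested, with 1 library of each sex.

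CNS tissues held more signatures than non-neural tissues at equal depth. Errors of 1 base in signatures with 10 times the beads do not account for the difference. Without the signatures 1 base from such a signature, 0.967 of the difference was kept (jackknife SE 0.0156), at 0.5 of the depth. Other errors, of more bases or of less abundant signatures, were not tested. Whether a few abundant signatures take most of the counts could not be settled. Without the 100 most abundant signatures 0.755 of the difference was kept (SE 0.00729), within its error of the bound set before the test. The requirement that the value pass the bound by its error was added after the value was seen. The depth that remained was lower, and 0.885 was kept against the difference at 0.5 of the depth. A greater variety of transcripts in CNS tissue stays possible and was not told apart from a more even spread of their abundance.

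The count of signatures that differed between CNS and non-neural tissues was 22706. As many were reached in 1 of 100 splits of the 33 tissues, the real one, the smallest share that 100 splits allow. The highest other split gave 6675, so random splits of the tissues do not account for the count. Other groups of related tissues were not tried. Other splits called a median of 2080, so splits that mix the classes also yield many calls.

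The count of 14 signatures that differed by sex did not stand apart. Exchanging the libraries within tissues gave as many or more in 27 of 30 draws, the real one included, with 37 in the highest other draw, so chance is not excluded for the count. Single signatures can be judged by the number of libraries with a count. GATCTTCAGTATGCTGCTCC and GATCCAAGCCCTTCATCTTC differed by 28 and 24 libraries between the sexes. In 10000 exchanges, no signature reached either difference, and the highest was 21. A difference of 17, as for GATCTGTGTGGAGCTTTGTG, was reached by some signature in 805 exchanges. The first and second were called in 8 of 9 alternative settings and not with W runs only. The third was called in 6, and not with W runs only, with both run types or with DESeq2. Testis and prostate were not in this test and held at most 1.715 CPM of the first or second.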

How the results depend on the processing

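The settings of signatures with beads in both run types, of signatures counted in at least 10 tissues, of edgeR with a prior dispersion trend and of the rank permutation were chosen after the data were seen. So were the covariate for T runs in the tissue pairs, leaving out the libraries of each CNS region and the alternatives for tissue enrichment. No paired analysis was possible because the replicate numbers follow only the order of deposit and link no libraries. The fit of the 70 libraries has a term for tissue, and CNS and non-neural tissues were compared with the sexes summed. The cause of each change was not tested. Giving signatures to genes in other ways and another pseudocount were not run. Leaving out each library in turn was not run for tissue enrichment. Bead totals kept every count within 1.5 times except that for liver, but moved the higher and lower calls to 35 and 18 for heart and 2 and 7 for kidney by sex. A call covers an adjusted p under 0.05.

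Totals for brown against white fat, heart, kidney regions and intestine were 63, 64, 16 and 57. W runs only gave 34, 22, 1 and 22 calls, the edgeR fit of the 4 libraries compared 0 in each (1021, 215, 127 and 476 at an unadjusted p under 0.05), and no filter beyond a count of 1 gave 23, 36, 10 and 19. edgeR with a dispersion trend gave 1, 6, 0 and 1, and DESeq2 274, 617, 292 and 290. At an unadjusted p under 0.05 the main edgeR test had 2106, 1671, 1580 and 1528. For kidney, edgeR with both run types gave 0 (1224 unadjusted), the trend had 1090 unadjusted, and the T-run covariate gave 3, of which 2 were among the 16. Leave-one-out totals were 23 to 33 for fat, 18 to 69 for heart, 7 to 28 for kidney and 19 to 34 for intestine. DESeq2 shared 12, 23, 14 and 12 of its calls with the main test, and 241, 574, 241 and 280 of its calls came from fits that had not converged.

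The CNS region total, in both directions, fell to 2316 with W runs only, 1201 with no filter and 1594 with DESeq2. The numbers per region that follow count higher calls only. In W runs only, amygdala had 142, cerebellum 234, cortical mantle 41, hippocampus 279, hypothalamus 157, midbrain 74, olfactory bulb 395, olfactory tubercle 208, spinal cord 488, striatum 134 and thalamus 138. With no filter, in that order, the numbers were 57, 105, 30, 128, 88, 60, 146, 87, 358, 62 and 69. DESeq2 gave 99, 56, 49, 80, 105, 63, 73, 129, 114, 67 and 55. With a dispersion trend amygdala had 303 and striatum 304. The 22 CNS libraries alone gave 258 for cortical mantle, and both run types gave 367 for hippocampus and 109 for thalamus. Leave-one-out counts, over the libraries of the region and the female spinal cord library, were 329 to 471 for amygdala, 122 to 361 for cerebellum, 44 to 96 for cortical mantle, 90 to 456 for hippocampus and 88 to 342 for hypothalamus. They were 102 to 244 for midbrain, 133 to 618 for olfactory bulb, 201 to 412 for olfactory tubercle, 326 to 719 for spinal cord, 144 to 392 for striatum and 96 to 212 for thalamus.

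The sex total of 14 became 31 without the tissues with T runs, 3 with a dispersion trend, 5 with no filter and 283 with DESeq2. W runs only gave 10, of which 4 were among the 14. The kidney total of 13 became 1 with W runs only, 5 with both run types, 3 with the T-run covariate, 1 without the cortex pair, 6 without the medulla pair, 1 with no filter and 56 with DESeq2. The liver total of 12 became 7 with bead totals, 1 with W runs, 7 with both run types, 0 with no filter, where edgeR had 804 at an unadjusted p under 0.05, and 290 with DESeq2. Leave-one-out of the male liver libraries gave 6 for each.

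CNS against non-neural totals of 22706 became 13855 with both run types, 10205 in at least 10 tissues, 43015 with no filter, 13330 with DESeq2 and 13454 by rank permutation, and DESeq2 shared 12243. Tissue enrichment changed from 168669 to 109819 with W runs, 107625 with both run types, 297975 with a trend and 6138 with DESeq2. Median agreement within a tissue, 0.507 in the main setting, became 0.663 with Pearson's correlation, 0.567 with both run types and 0.488 with W runs only. Between tissues the medians became 0.468, 0.411 and 0.363, against 0.358 in the main setting. Single libraries with both run types gave 666 of 1213. The signature number in CNS kept its direction and p under 0.05 in every setting, with differences of 4564 to 14036.

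DESeq2 reversed GATCCCACCCACCCACCCAC for sex (-10.74), GATCAACAAATCTCCTAGTC (-1.06) and GATCAGGGCAATGGTCACTG (12.88) for kidney, and GATCGTGATTGTGCTGGGCC (37.02) for liver. Over 381 combinations of a printed signature and a setting, 255 kept direction and call, 122 kept direction without the call and those 4 reversed. With edgeR none reversed. Depth limited the values below about 1.55 CPM, where a count of 0 says nothing.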

Other observations

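The comparison of single libraries with the other tissues was planned, and the settings of signatures with beads in both run types and of 1-base neighbours were chosen after the data were seen.

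The 11 tissues with 1 library have no replicate, so their values carry counting error only. A signature was listed for such a library when it had at least 100 CPM and at least 10 times the level of the highest other tissue. Testis had 619 such signatures, of which 467 had beads in both run types and 222 had no count elsewhere. Prostate had 148 (31 with beads in both run types), stomach 133 (48), placenta at E18 131 (59), cervix and vagina 57 (17), and the left lobe of the liver 44 (8). Uterus had 23 (8), uterus at E18 of pregnancy 20 (9), ovary 19 (12), the embryo 12 (5) and mammary gland 7 (2). Together they made 1213, and 666 with beads in both run types. In testis, GATCCCAAAATGAGATAGCC had 13814 CPM (95% exact Clopper-Pearson interval 13665 to 13965), against 16.4 CPM in thymus, the highest other tissue. In placenta, GATCCTGCACTCAAGTCCCT had 51137 CPM (interval 50884 to 51390), against 510 CPM in the uterus at E18 of pregnancy. In stomach, GATCCTCGGGGATGTCTTCC had 117574 CPM (interval 117144 to 118004), against 3904 CPM in thigh skeletal muscle.

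Some called signatures were 1 base from a more abundant one. Among the 74864 signatures tested in the 70-library fit 20.3% differed by 1 base from a signature with at least 10 times the beads. The share was 23.5% of those higher in brown fat and 3.45% of those higher in white fat, and 35.3% of those higher in atria and 15.4% of those higher in ventricles. It was 6.67% of those higher in kidney cortex, 7.89% of those higher in small intestine and 26.3% of those higher in large intestine. Among CNS regions it was 23.0% of those called higher and 10.0% of those called lower. In another fit, of CNS against non-neural tissues, it was 10.9% of those higher in CNS and 27.2% of those lower. The single call in medulla had no such neighbour. For sex it was 28.6% of those higher in male and 14.3% of those higher in female libraries. For a larger male excess it was 20.0% in kidney and, in a further fit, 33.3% in liver, and for a smaller one 0 in both. The share of 20.3% does not apply to these other fits.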
